A study of Homo sapiens with 6 samples.

How the data were processed

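Gene expression was measured in CD133-positive cells from 3 glioblastoma xenograft lines, human brain tumours that were grown under the skin of a host animal. CD133, the product of PROM1, is a surface protein used to enrich glioblastoma stem cells. Per the labels' protocols, tumours were dissociated, cells were enriched on CD133 microbeads, and the cultures were kept short-term in neurobasal medium with EGF and bFGF. Each line gave 1 sample treated with DMSO, the solvent control, and 1 sample treated for 24 h with tipifarnib, an inhibitor of protein farnesyltransferase, together with RO4929097, an inhibitor of gamma-secretase, the protease that releases the active Notch fragment. The labels disagree on the dose: the series text gives 100 nM of each drug and the treatment protocol gives 100 µM of each. No value in the data settles this, so the concentration behind every change below is open. Samples with 1 drug alone were not analysed here.

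Total RNA was hybridised to 6 Affymetrix Human Gene 1.1 ST arrays, 1 per sample, and the array design was taken from the probe annotation table. The labels name a One-Cycle labelling kit. The deposited values are log2 intensities per probe set made by RMA, which corrects background, normalizes and summarises probes, in Affymetrix Expression Console 1.1, per the submitters' processing notes. Those notes also name hg19 and limma without giving their role. The 6 columns ranged from 1.51 to 13.6 and had nearly but not exactly equal quantiles: the medians lay between 5.18 and 5.29, and the SD was 2.40 on the treated array of line 3 against 2.46 to 2.48 on the others. RMA compresses small differences at low intensity. No detection calls were used here, so it is unknown which probe sets stood above background. For arrays there is no sequencing depth, and the number of arrays limits the precision.

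Of 33297 probe sets, 19181 had 1 gene symbol in the platform annotation, 2055 had several and 12061 were not listed there. Symbols were checked through the Entrez identifier against the RefSeq gene table of GRCh38, where 19143 matched and 0 changed. Probe sets with several symbols or none were left out of the gene tests. The remaining probe sets covered 17958 genes, 895 of them with more than 1 probe set, for which the probe set with the highest mean over all arrays was used. Genes were tested when that mean was at or above the 30th percentile of all probe sets, a log2 intensity of 3.99, which left 14514 genes.

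The comparison was combination against DMSO with the xenograft line as a block, since both samples of a line come from the same xenograft line. This pairing comes from the sample names, and the arrays bore it out: deviations from the group mean correlated between the arrays of the same line at 0.516, 0.463 and 0.586 and at most at 0.0891 between arrays of different lines. The fit used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. It had 2 residual degrees of freedom and gained 7.06 from the shared prior. The labels name 3 separate xenograft lines and do not say whether a line was cultured more than once. Gene p-values of the limma fit therefore measure the spread between these 3 pairs, moderated by the prior shared over genes. Camera p-values at a preset correlation compare a list with the other genes, so they do not measure the spread between pairs. A change below is the mean over lines of combination minus DMSO in log2 units, given with the SD of the 3 line differences, and adjusted p-values are those of this limma fit unless another test is named.

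Before the data were examined, 35 gene lists were fixed for pathways, cell states and other cell types. They were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists with at least 5 tested genes. The list of macrophage and microglia markers fell short of that number. Also fixed were the genes to be named: up to 12 called genes with the largest rise and 12 with the largest fall that moved the same way in all lines, up to 4 called members of each list by smallest p (or up to 2 members where none was called), 35 genes named always, and up to 6 genes with the largest spread between lines among the brighter genes. Genes named outside this rule are marked as chosen after their values were seen. Among the genes named always, PROM1 and DLL3 lay under the intensity filter. Some of these genes and 1 of the 34 lists are not reported here.

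Differences within 1 line rest on 1 array per condition and were described without a test. Most alternatives changed 1 choice at a time: the block, a random block by duplicateCorrelation, the trend, robust moderation, the filter, the rule for several probe sets, a new quantile normalization, centring on the array median, leaving out each line, the thresholds, an unmoderated paired test, and camera with an estimated correlation, its rank form and fry, which tests whether a list moves one way without setting it against other genes. An exception was 1 fit that left out both the line term and the DMSO array of line 1. With a random block, robust moderation and the unmoderated test, lists were tested by camera on the t values of the fit. Their list results therefore hold a changed list test besides the named choice. Fits with a line left out lean more on the prior than the main fit. Camera with an estimated correlation rests on the 2 residual degrees of freedom and is adjusted over 34 lists. It therefore had little power, and a miss in it cannot tell a shifted list from an unshifted one. The fit was tested on simulated data with 14514 genes in the same design, of which 200 were changed singly and 100 more belonged to lists shifted by 0.3 log2 units. It recovered 34.3% of genes changed by 0.5 log2 units, 95.5% of those changed by 1 and 100% of those changed by 2, and called 6 of the 100 shifted list genes; 12 unchanged genes were called, 7.02% of all 171 calls. It also found 5 of 5 shifted lists and called 0 of 15 unshifted ones. The simulated genes varied independently of each other. In the real lists the estimated correlation was 0.74 for G2/M, 0.348 for G1/S and 0.0076 for hypoxia and glycolysis. The simulation therefore does not show how often camera calls an unshifted list of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.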

Results

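The data were 6 expression arrays of CD133-positive glioblastoma cells from 3 xenograft lines, 1 treated with DMSO and 1 with tipifarnib plus RO4929097 for 24 h in each line. The design asks how glioblastoma stem cells respond to a farnesyltransferase inhibitor given together with a gamma-secretase inhibitor. All values are log2 intensities, and changes are given in log2 units as the mean ± SD of the 3 lines (n = 3). The PROM1 probe set, which measures the transcript of CD133 itself, lay under the intensity filter at 3.37 over all arrays, the 17.6th percentile of probe sets, with 3.43 ± 0.20 in DMSO and 3.32 ± 0.14 under the combination.

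Under the combination, genes of cell division fell in all 3 lines. MKI67, the proliferation marker Ki-67, went from 8.40 in DMSO to 7.10, a change of -1.30 ± 0.11 (adjusted p = 4.19e-04). The mitotic kinases BUB1 and PLK1 changed by -1.37 ± 0.22 and -1.29 ± 0.25, and RRM2 and TK1, which supply deoxynucleotides, by -1.34 ± 0.40 and -1.27 ± 0.27. The replication-linked histone gene H2BC14 had the largest fall, -1.50 ± 0.54. The other genes among the 12 largest falls were PBK, DLGAP5, KIF2C, HMMR, SHCBP1 and NUF2, at -1.37 to -1.27, and all of these act in mitosis or are expressed with it. Rises were smaller and fewer. SLC7A11, the cystine and glutamate transporter, rose by 1.18 ± 0.65, and ASNS, which makes asparagine, by 0.85 ± 0.37. NRP2, a semaphorin and VEGF co-receptor, rose by 0.82 ± 0.12, GABRE, a GABA receptor subunit, by 0.83 ± 0.07, and ID4 by 0.79 ± 0.16. Also among the 12 largest rises were SCG2, ZMAT1, ULBP1, a ligand of the natural killer receptor NKG2D, and C2orf66, at 0.74 to 0.97. ANKRD20A8P, DNM1P46 and RPPH1 completed them at 1.06, 0.87 and 0.82, but the first pair are pseudogenes with near-identical copies and RPPH1 is a small structured RNA, so their values are uncertain.

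**Figure D1:**
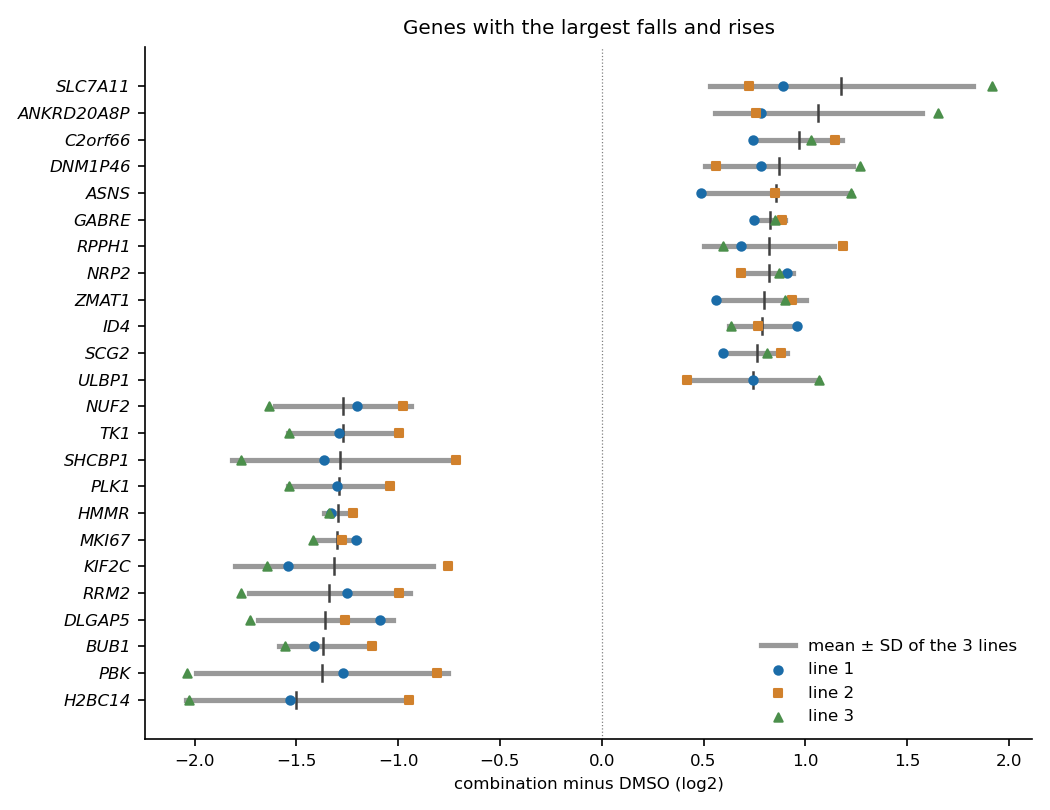
Combination minus DMSO in log2 units (horizontal axis) for the 12 genes with the largest falls and the 12 with the largest rises; symbols are the 3 xenograft lines, and the grey bar is their mean ± SD. All 24 genes moved the same way in every line, and line 2 had the smallest fall of PBK and KIF2C, at -0.81 and -0.76.

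In total, 744 of 14514 genes passed an adjusted p of 0.05 in the limma fit, 204 higher and 540 lower under the combination, and all 744 moved the same way in all 3 lines. Of the calls, 60 exceeded 2-fold, 2 higher and 58 lower. Among all tested genes 5977 (41.2%) moved the same way in every line, where 25% is expected by chance. The median over all genes was -0.01. Centring each array on its median gave 110 higher and 676 lower, so the share of higher calls was 27.4% as deposited and 14.0% after centring. The count rested on the line block and on moderation: 40 genes passed without the line term, 267 with the line as a random block, 258 without the intensity trend, and 0 with an unmoderated paired test, which had 1788 genes at an unadjusted p under 0.05. Of the 70 called genes that follow the naming rule, 12 passed without the line term.

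The list of G2/M and mitosis genes had the largest shift, with all 27 measured members lower, also when adjusted over the list alone. Its median change was -1.02, with line medians of -1.10, -0.77 and -1.30 (camera adjusted p = 2.10e-40, adjusted p = 0.643 with an estimated correlation, fry adjusted p = 0.0587). Camera with an estimated correlation has 2 degrees of freedom, and its unadjusted p for this list was 0.0767. CDC20, which activates the anaphase-promoting complex, changed by -1.27 ± 0.18, HMMR by -1.30 ± 0.07, AURKA by -1.05 ± 0.30 and CCNB1, the mitotic cyclin, by -0.81 ± 0.29. Of 28 measured G1/S and DNA replication genes 19 were lower and 0 higher over all genes tested, and 28 were lower adjusted over the list alone. The median was -0.50 and the line medians were -0.41, -0.49 and -0.61 (camera adjusted p = 6.20e-26, adjusted p = 0.643 with an estimated correlation, fry adjusted p = 0.0587). MCM10 and CDC6, which act in the loading and firing of replication origins, changed by -1.09 ± 0.11 and -0.98 ± 0.10, DTL by -1.03 ± 0.20 and MCM2 by -0.41 ± 0.16, the last not called without line 2 or without line 3. UHRF1 fell by 0.82 ± 0.10 on its brighter probe set, but its probe sets disagreed in direction and the mean of them was not called. Histone genes had 2 of 15 members lower, 6 when adjusted over the list alone, and a median of -0.29 (line medians -0.49, -0.06 and -0.30, camera adjusted p = 0.00308, adjusted p = 0.643 with an estimated correlation). The called members were H1-5 at -1.08 ± 0.52 and H2BC8 at -0.57 ± 0.23, the latter not called without line 1 or without line 3, and histone genes have near-identical copies that share probes.

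The list of CDK inhibitors and quiescence genes passed in the higher direction with a median of 0.15, although 0 of its 11 measured members were called over all genes and 5 were when adjusted over the list alone, 4 higher and 1 lower (camera adjusted p = 0.0211, adjusted p = 0.643 with an estimated correlation). CDKN1B, the inhibitor p27, was at 0.38 ± 0.31 (adjusted p = 0.0885) and KLF6 at 0.29 ± 0.16 (adjusted p = 0.0931). The list missed the threshold without line 2 (adjusted p = 0.110) and without line 3 (adjusted p = 0.0814). The p53 targets had a median of 0.10 with line medians of 0.11, 0.09 and -0.004 (camera adjusted p = 0.0370, adjusted p = 0.643 with an estimated correlation). The 1 called member of 18 was ZMAT3 at 0.30 ± 0.09, against 3 adjusted over the list alone, and CDKN1A, the inhibitor p21, was at 0.08 ± 0.08 (adjusted p = 0.622). This list missed the camera threshold without line 1 (adjusted p = 0.0504), without line 2 (adjusted p = 0.110) and after median centring (adjusted p = 0.0606). It also missed without the intensity trend (adjusted p = 0.0845). Camera on the t values of the fit missed it with a random block (adjusted p = 0.0540), robust moderation (adjusted p = 0.0578) and the unmoderated paired test (adjusted p = 0.495). Those misses cannot be told from an effect of the changed list test.

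**Figure D2:**
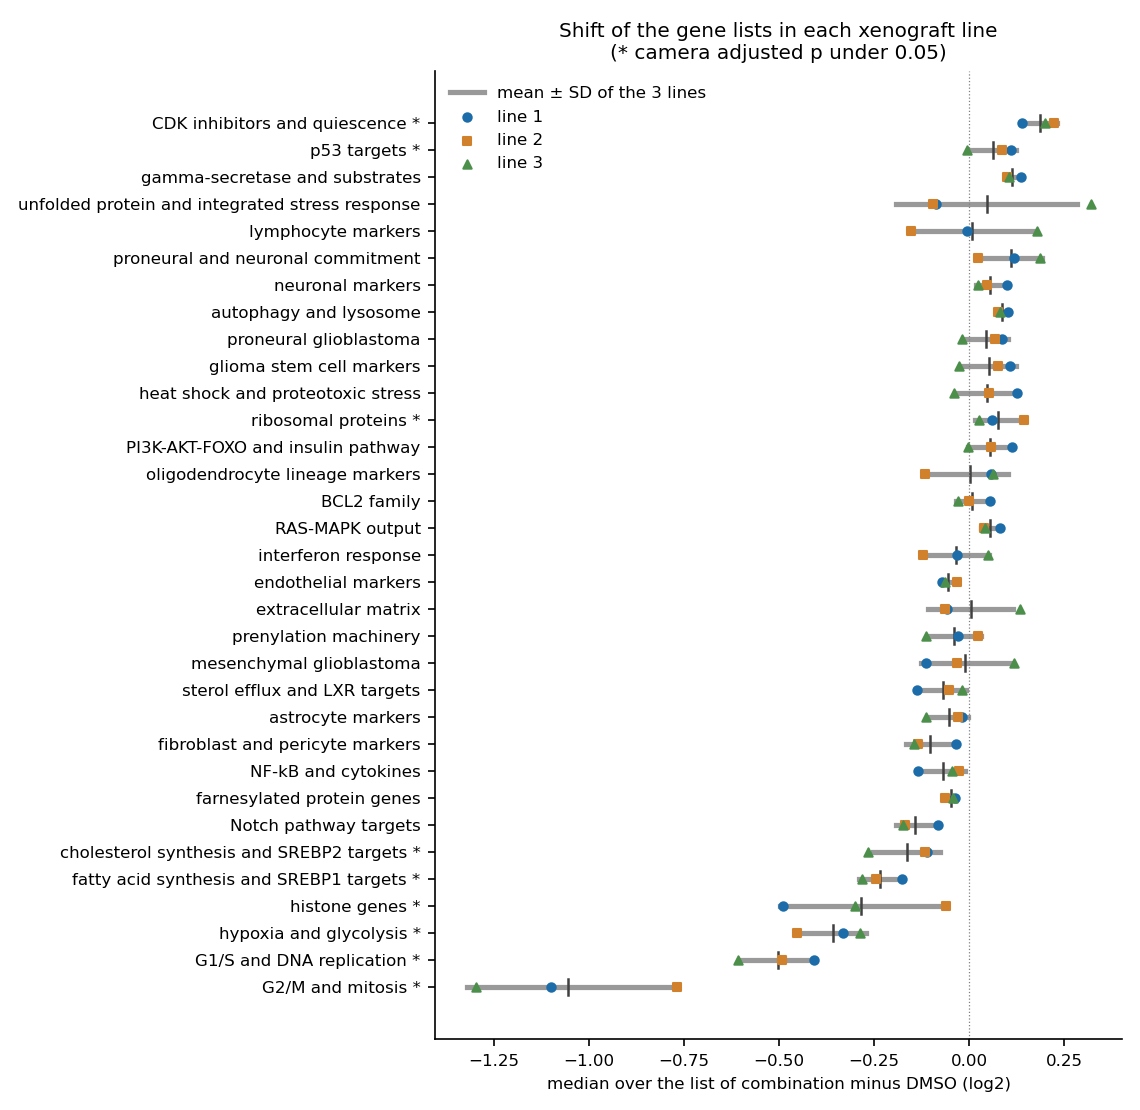
Median of combination minus DMSO in log2 units (horizontal axis) over each of 33 tested gene lists, with 1 symbol per xenograft line and a grey bar for the mean ± SD of the 3 lines; stars mark a camera adjusted p under 0.05. The G2/M and mitosis list lay lowest in every line, at -0.77 to -1.30.

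Glycolytic and sterol or lipid genes were lower as well. Of 17 measured hypoxia and glycolysis genes 9 were lower and 0 higher, 12 when adjusted over the list alone, with a median of -0.33 and line medians of -0.33, -0.45 and -0.29 (camera adjusted p = 2.68e-09, adjusted p = 0.643 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, changed by -0.87 ± 0.26, ADM, which encodes adrenomedullin, by -0.69 ± 0.13, HK2, a hexokinase, by -0.61 ± 0.11 and SLC2A1, the glucose transporter GLUT1, by -0.56 ± 0.07. Fatty acid synthesis and SREBP1 targets had 5 of 12 members lower over all genes, and 6 lower and 1 higher adjusted over the list alone, with a median of -0.22 (camera adjusted p = 4.61e-04, adjusted p = 0.643 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, changed by -0.33 ± 0.05, the desaturases SCD and FADS2 by -0.31 ± 0.04 and -0.37 ± 0.09, and ELOVL6 by -0.32 ± 0.07; each of these 4 calls was lost when at least 1 line was left out. In the cholesterol synthesis and SREBP2 list 1 of 18 members was lower, FDPS, the synthase of farnesyl pyrophosphate, at -0.43 ± 0.17. Adjusted over the list alone 3 were lower and 1 higher, and the median was -0.18 (camera adjusted p = 0.0166, adjusted p = 0.643 with an estimated correlation). Without line 3 neither FDPS nor the list passed (list adjusted p = 0.119). Camera on the t values of the fit also missed the list, with the line as a random block (adjusted p = 0.0540) and with the unmoderated paired test (adjusted p = 0.522). HMGCS1 was at -0.20 ± 0.08 (adjusted p = 0.141) and INSIG1 at -0.25 ± 0.11 (adjusted p = 0.106). In the sterol efflux and LXR list LPCAT3 fell by 0.37 ± 0.10, a call lost without line 3, as 1 of 7 members, and the list did not pass (median -0.05, camera adjusted p = 0.529).

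For Notch, the pathway that gamma-secretase inhibition acts on, HES1 fell while most other targets did not pass. HES1, a repressor induced directly by Notch, went from 7.74 to 7.01, a change of -0.73 ± 0.13 (adjusted p = 0.00347), and kept its call with each line left out. MYC fell by 0.25 ± 0.08 (adjusted p = 0.0472, lost without line 1 or line 3), and the ligand gene JAG1 rose by 0.35 ± 0.19 (adjusted p = 0.0412, lost without line 3 and after median centring). Over the 20 targets 2 were lower and 1 higher, or 5 and 1 adjusted over the list alone, and the median of -0.14 did not pass (camera adjusted p = 0.0540, adjusted p = 0.643 with an estimated correlation). NRARP, a feedback inhibitor, was at -0.37 ± 0.20 (adjusted p = 0.112), HEY1 at -0.20 ± 0.11 (adjusted p = 0.150), and HES5, HEY2 and HEYL were at 0.05 ± 0.14, -0.01 ± 0.21 and 0.08 ± 0.11. HES5 and HEYL were dim, with DMSO means of 4.76 and 4.69, below the median of every array. Whether they stood above background is unknown, so their lack of change is hard to read. The receptors NOTCH1 and NOTCH3 were at -0.14 ± 0.11 and -0.13 ± 0.09, and CCND1 was at -0.22 ± 0.09 (adjusted p = 0.130) with probe sets that disagreed in direction. The neuronal commitment genes that Notch represses did not pass (0 of 12 called, median 0.09, camera adjusted p = 0.237); SOX11 was at 0.14 ± 0.08, ELAVL3 at 0.21 ± 0.15 and DLL1 at 0.10 ± 0.20. In the gamma-secretase and substrate list CDH2, N-cadherin, rose by 0.29 ± 0.10 as 1 of 12 members, a call lost under both rescalings and without line 1 or line 3, and NCSTN was at 0.15 ± 0.06 (list median 0.10, camera adjusted p = 0.0540, which passed with the stricter filter at 0.0420). The Notch list passed without the filter (adjusted p = 0.0221), with a stricter filter (adjusted p = 0.0420) and without line 3 (adjusted p = 0.0250), and its adjusted p reached 0.643 over all alternatives.

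**Figure D3:**
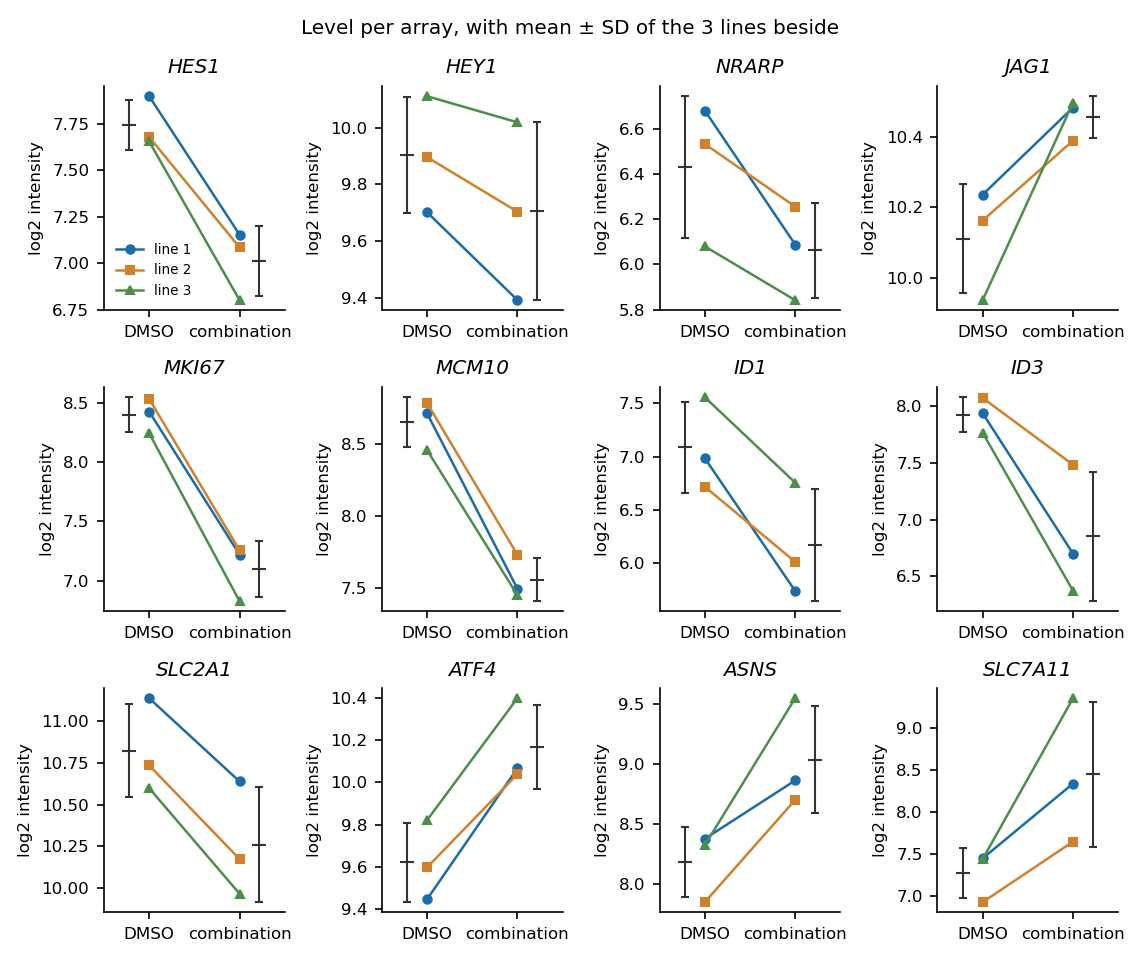
Log2 intensity (vertical axes) of 12 named genes in DMSO and under the combination, with 1 coloured line per xenograft line and black marks for the mean ± SD of the 3 lines. HES1 was lower in every line, at -0.59 to -0.85, whereas HEY1 and NRARP were lower in every line but did not pass the adjusted threshold.

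For farnesylation, the process tipifarnib inhibits, the genes of farnesylated proteins did not pass as a list (median -0.07, camera adjusted p = 0.389). LMNB1 and LMNB2, the B-type lamins, were its 2 called members of 18 and changed by -0.59 ± 0.18 and -0.59 ± 0.09. Of 8 prenylation enzyme genes 1 was called: ICMT, which methylates the prenylated cysteine, fell by 0.52 ± 0.11, a call lost without line 2 (list median -0.03, camera adjusted p = 0.389). The farnesyltransferase subunits FNTA and FNTB were at 0.09 ± 0.19 (adjusted p = 0.631) and -0.24 ± 0.21 (adjusted p = 0.192). Among 18 RAS-MAPK output genes 3 rose and 1, MYC, fell, with 5 and 3 adjusted over the list alone. PHLDA1 rose by 0.41 ± 0.04 and kept its call with each line left out, while DUSP4 at 0.36 ± 0.07 lost its call without line 1 or line 2, and the ERK feedback inhibitor SPRY2 at 0.29 ± 0.11 without line 1 or line 3, and both after median centring. DUSP6 and SPRY4 were at -0.03 ± 0.09 and 0.12 ± 0.13, and the list did not pass (median 0.01, camera adjusted p = 0.258). THBS1, a matrix glycoprotein, fell by 0.90 ± 0.44 and ACTA2, smooth muscle actin, rose by 0.33 ± 0.07, calls lost without line 2 and without line 3 respectively. RHOB was at 0.00 ± 0.30. The PI3K, AKT and FOXO list had 0 of 13 members called (median 0.04, camera adjusted p = 0.301), and its first members by p were PIK3IP1 at 0.43 ± 0.44 and IRS2 at 0.23 ± 0.08.

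Amino acid and stress genes moved in both directions. In the list of the unfolded protein and integrated stress response 3 of 20 members rose and 2 fell. ATF4, the transcription factor of the integrated stress response, rose by 0.55 ± 0.09 (adjusted p = 0.00300), together with SLC7A11 (adjusted p = 0.0101) and ASNS (adjusted p = 0.00589). DDIT4, an inhibitor of mTORC1, changed by -0.66 ± 0.09, and SDF2L1, an ER chaperone gene named after its values were seen, by -0.54 ± 0.30. The list did not pass (median 0.10, camera adjusted p = 0.389) and its line medians were -0.09, -0.09 and 0.32; without line 1 it passed (adjusted p = 0.00186). Heat shock genes had 0 of 9 members called (median 0.04, camera adjusted p = 0.389), with HSPA1A at 0.22 ± 0.32 and DNAJB1 at 0.16 ± 0.20. In the BCL2 family HRK, a pro-apoptotic member, rose by 0.73 ± 0.12 as 1 of 14 (list median 0.04, camera adjusted p = 0.389). Autophagy and lysosome genes had 0 of 19 called and a median of 0.08 with line medians of 0.10, 0.08 and 0.08. That list missed the camera threshold (adjusted p = 0.0788, adjusted p = 0.643 with an estimated correlation) and passed fry (adjusted p = 0.00459), camera with the stricter filter (adjusted p = 0.0420), camera after quantile normalization (adjusted p = 0.0429) and the unmoderated test (adjusted p = 0.00859); LAMP2 was at 0.27 ± 0.15 and GLA at -0.37 ± 0.28. Ribosomal protein genes passed with 0 of 17 members called and a median of 0.04 (camera adjusted p = 0.0166, adjusted p = 0.643 with an estimated correlation), and -0.01 under median centring, which shifts all genes alike, so the sign of so small a change is not settled. The call was lost there (adjusted p = 0.141), without line 2 (adjusted p = 0.214), after quantile normalization (median 0.02, adjusted p = 0.109) and without the intensity trend (adjusted p = 0.0845). RPL5 was at 0.14 ± 0.12 and RPL10A at 0.13 ± 0.02.

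Stem cell and lineage genes showed single large changes rather than shifts of whole lists. ID3 and ID1, inhibitors of differentiation that are induced by BMP signals, changed by -1.07 ± 0.43 and -0.92 ± 0.29 (adjusted p = 0.00409 and 0.00439), the 2 called members of 17 glioma stem cell markers. SOX2, OLIG2 and NES were at 0.10 ± 0.10, 0.07 ± 0.07 and 0.09 ± 0.08, none of them called. The list did not pass (camera adjusted p = 0.476, direction higher), with a median of 0.07 and a mean of -0.05. Among 14 astrocyte markers 4 were lower: SPARCL1 at -0.81 ± 0.10, ALDOC at -0.67 ± 0.25, AGT at -0.62 ± 0.15 and GJA1 at -0.36 ± 0.13. AGT lost its call without line 2, and GJA1 without line 1 or line 3, and ALDOC is also a glycolytic enzyme. The list missed camera (median -0.05, adjusted p = 0.241) and passed fry (adjusted p = 0.0197), and GFAP was at 0.14 ± 0.18. NEFH, a neurofilament subunit, fell by 0.55 ± 0.08 as 1 of 13 neuronal markers, a list with a median of 0.08 and a mean of -0.01 (camera adjusted p = 0.626, direction higher). Oligodendrocyte lineage markers had 0 of 11 called (median 0.04, camera adjusted p = 0.735), with CNP at -0.18 ± 0.20 and CSPG4 at -0.21 ± 0.05. The proneural glioblastoma list had 0 of 12 called (median 0.07, camera adjusted p = 0.389), with TCF4 at -0.13 ± 0.03. The mesenchymal glioblastoma list had 0 of 19 called (median -0.04, camera adjusted p = 0.711), with S100A11 at 0.25 ± 0.08 and FOSL2 at -0.35 ± 0.06. LOX and IL6, 2 members of that list, were among 30 genes that were bright in the DMSO array of line 1 alone.

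Lists for signalling from outside the cell and for other cell types did not pass. Interferon response genes had 1 of 17 lower, IFI6 at -0.36 ± 0.10, a call lost with any line left out (median 0.00, mean -0.04, camera adjusted p = 0.735, direction lower). NF-kB and cytokine genes had 0 of 13 called (median -0.07, camera adjusted p = 0.491); IL6 was at -0.83 ± 0.99, with -1.98 in line 1 against -0.21 and -0.30, and CXCL2 was at -0.14 ± 0.17. Extracellular matrix genes had 0 of 15 called (median -0.01, camera adjusted p = 0.896, higher by the test although median and mean lay below 0), with LUM at -0.59 ± 0.47 and LAMC1 at 0.18 ± 0.12. Endothelial markers had 1 of 8 lower, KDR at -0.67 ± 0.28, a call lost without line 2 (median -0.004, camera adjusted p = 0.389). Fibroblast and pericyte markers had ACTA2 as the 1 called member of 9 (median -0.06, camera adjusted p = 0.626). Lymphocyte markers had 0 of 5 called (median 0.10, camera adjusted p = 0.697), with CD8A at 0.14 ± 0.20 and GNLY at 0.16 ± 0.41. The macrophage and microglia list had too few tested genes; its member CD68, a lysosomal protein, fell by 0.46 ± 0.21, a call lost without line 1 or line 2 and after quantile normalization.

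The lines differed in the size of their response, which rests on 1 array per condition and has no test. Line 1 had 113 genes beyond 2-fold, 1 higher and 112 lower, line 2 had 34, 10 higher and 24 lower, and line 3 had 166, 21 higher and 145 lower. In line 1, 30 of the 112 lower genes were those whose level in its DMSO array exceeded all 5 other arrays by at least 1 log2 unit, and 1 of those 30 was called over the 3 lines. The other arrays include the treated array of line 1, so by this definition all 30 had to be among its lower genes. The responses correlated across 14514 genes at a Pearson r of 0.437 between lines 1 and 2, 0.391 between lines 1 and 3 and 0.295 between lines 2 and 3 (Spearman 0.408, 0.366 and 0.202). Genes are not independent replicates, and no array is shared between these differences. With the filter raised to the median of all probe sets the 3 Pearson values were 0.538, 0.530 and 0.457. In DMSO, 113 genes differed by at least 2-fold between lines 1 and 2, 296 between lines 1 and 3 and 256 between lines 2 and 3, of which 32, 174 and 171 differed the same way under the combination too.

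Among genes at or above the median level of the genes tested, those with the widest spread of response between lines included ALCAM, a cell adhesion molecule, at -2.62 in line 1, -0.07 in line 2 and -0.29 in line 3. NUPR1, a stress-induced gene, was at -0.24, 0.58 and 1.44, and FAM86B2-DT at -0.24, -0.05 and 1.41. KRT18, a keratin, was at -0.30, -1.20 and 0.74, and the histone genes H3C12 and H4C3 were at -1.50, 0.26 and -0.71 and at -0.27, 0.56 and -1.40. None of these 6 genes passed over the 3 lines, and the differences between lines were not tested.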

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

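The comparisons of the 30 bright genes with other arrays, of the noise of that array, of the marker genes and of what remained after treatment were chosen after the pattern had been seen, as was the value of the mitosis list without line 1; the other tests were chosen before. The lists and genes below were picked because lines moved in opposite directions, and the differences between lines were not tested.

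Among probe sets outside the gene tests, 28 of 6184 that the annotation does not list were called in the same limma fit, 20 higher and 8 lower, and 22 of 1648 with several gene symbols were called, 8 higher and 14 lower. In the list of lymphocyte markers the line medians spanned 0.332 log2 units, from -0.15 to 0.18 over 5 tested genes. In the mesenchymal glioblastoma list they spanned 0.231, from -0.11 to 0.12. The responses of H4C3 spanned 1.96, from -1.40 to 0.56, and those of KRT18 spanned 1.94, from -1.20 to 0.74. The groups of 3 arrays were too small for a check of outlying samples.

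Line 1's DMSO array held 30 genes at least 1 log2 unit above all 5 other arrays and 0 genes as far below them, while the other arrays held 0 to 6 above and 0 to 8 below. The highest were CLDN1 at 9.23 against a mean of 3.84 ± 0.13 on the other 5, ANPEP at 9.52 against 5.04, PLAC8, LOX and KYNU, named here after their values were seen. Noise of that array stays open, since its correlations with the other DMSO arrays, 0.992 and 0.983, lay on both sides of the 0.985 between those arrays, and 30 of 14514 genes hardly move such a correlation. Human fibroblasts, endothelial and immune cells are argued against by their markers that were as dim on the other arrays as the bright genes. The median excess of these markers over the other DMSO arrays was at most 0.134 in the 4 lists. In the bright genes it was 1.999 over the 4 arrays of lines 2 and 3. COL1A1 was at an excess of -0.02, COL3A1 at 0.303 and DCN at -0.53 (an SD of 0.680 over the 7 dim fibroblast markers). VWF was at 0.19 and PTPRC at 0.103. CDH5 at 1.09 and MCAM at 0.86 were higher, but also on the treated array of line 1 (6.05 and 8.28 against 6.21 and 8.23). Cells of the host animal stay open, since the probe sets are made for human transcripts. LOX and IL6, of the mesenchymal glioblastoma list, are among the 30, so mesenchymal cells without these markers are not covered. Epithelial cells stay open too, since 15 such markers had a median excess of 0.0951 but CDH3 is among the 30. RNA of other cells, epithelial or of a kind outside these lists, may account for the 30 against 0, and so may a subpopulation of line 1 lost under the combination. The treated array of line 1 kept no excess in the 30 genes (a median of -0.0157 over lines 2 and 3). That value cannot decide between them, since the genes were picked as at least 1 log2 unit lower on that array than in DMSO.

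The fall of the mitosis genes was weighed against the scaling of the arrays and against that array of line 1. Quantile normalization left the list's median at -1.01 and median centring at -1.08, against -1.02 as deposited. That argues against the scale differences left between the deposited arrays as its cause. The array medians of 5.18 to 5.29 left little room for another outcome, and the normalization within RMA was not tested. Without line 1 the median was -1.03, which argues against the extra RNA in its DMSO array. A response of dividing cells to the drugs remains as a hypothesis, found and tested on the same arrays, and whether fewer cells were dividing or each held less of these transcripts was not tested.

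The number of genes beyond 2-fold in line 3, 166, was 149 after quantile normalization, which argues against the narrower distribution of its treated array as the whole cause. After median centring it was 214. A stronger response of line 3 stays open and untested, since each condition had 1 array.

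The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 744 genes and was the 1 split to reach that number; the highest other split called 13. It called 9 lists, again the 1 split with as many, and the highest other called 8, or 6 among the 3 other splits that part every line. By construction every other split keeps part of the real contrast, either the difference within 1 line or 2 lines in the real direction against 1, and the G2/M and mitosis list passed camera in all 9 of them and the G1/S list in 8. In the 3 other splits that part every line the G2/M median was at most 0.52 in size, against -1.02 in the real one. Lists that the real split did not call also passed camera in other splits. Mesenchymal glioblastoma and the unfolded protein and integrated stress response passed in 4 of 9 each, 2 of them parting every line.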

How the results depend on the processing

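The fit without line 1's DMSO array was chosen after seeing the data; the other alternatives were chosen before. Called lists kept direction and call in 114 comparisons with an alternative, missed the threshold in 29 and changed sign in 1: ribosomal proteins, at -0.0101 after median centring, by its construction. Called named genes kept both in 834 and missed the threshold in 286. The tally of lists leaves out fry, the changed thresholds and the fit with every probe set tested. Its random-block, robust and unmoderated entries also hold the changed list test. The count of called genes, 744, was 40 with no replicate block for the line, 267 with a random block, 258 without the trend, 1320 at an adjusted p under 0.10, 60 with a 2-fold minimum and 0 in the unmoderated paired test (1788 at an unadjusted p under 0.05), which has 2 degrees of freedom. With no line term and without line 1's DMSO array it was 0 (1056 at an unadjusted p under 0.05 in limma); the missing block is in this fit too. It ranged from 526 to 665 with a line left out, and 527, 434 and 501 of the 744 genes were shared without lines 1, 2 and 3. Those fits gained 64.7, 9.42 and 8.19 degrees of freedom from the prior, against 7.06 in the main fit. Calls kept or lost with a line left out therefore rest largely on moderation, which was of unequal strength. The count of lists, 9, was 1 with a 2-fold minimum, 5 in the unmoderated test, 0 with an estimated correlation (1 at an unadjusted p under 0.05 among the lists; 9 by rank) and 4 with fry (hypoxia and fatty acid synthesis among those called by camera, with autophagy and astrocyte markers; the other 7 called lists missed it at 0.0587 to 0.340), and 6 to 9 with a line left out; among the lists, leaving out the block changed the call of p53 targets only, while 58 of 70 called named genes lost theirs (p53 targets: adjusted p = 0.0502 without it, up to 0.643 in other alternatives). The Notch median passed at -0.14 without a filter and at -0.19 with the stricter filter, ranged from -0.16 to -0.11 with a line left out, and was -0.0685 (adjusted p = 0.554) with no line term and without line 1's DMSO array. Genes beyond 1.5-fold numbered 410, 387 and 1027 in lines 1 to 3. Response correlations were 0.538, 0.530 and 0.457 with the stricter filter, and for lines 2 and 3 0.217 without a filter and 0.373 after quantile normalization. Camera with an estimated correlation rests on 2 degrees of freedom too, so its 0 calls do not decide whether lists shifted. Apart from the constructions named, the cause was not tested. Signal over background is unknown, so the reading of dim genes such as PROM1 is limited.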

Other observations

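The lists in this part were written after the named genes and some other single genes had been seen, and before the lists themselves were tested. They leave out the gene that prompted them, but not every gene seen before. The tests of the NRF2 targets by line and gene by gene, and the comparison of the chaperones with the size of the fall of SDF2L1, were chosen after those lists' results were seen.

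Genes of the clustered protocadherins, neuronal adhesion molecules encoded in 3 neighbouring clusters, were higher under the combination. PCDHA10, picked after its values were seen, rose by 0.72 ± 0.05 (adjusted p = 0.00146). Of 26 other measured members 10 rose and 0 fell, 25 lay above 0, and the median was 0.39 with line medians of 0.41, 0.40 and 0.37. Among 11 alpha cluster genes 7 rose, among them PCDHA4 by 0.55 ± 0.04 and PCDHA6 by 0.55 ± 0.08. Among 14 beta cluster genes 3 rose: PCDHB9 by 0.55 ± 0.16, PCDHB12 by 0.54 ± 0.14 and PCDHB13 by 0.59 ± 0.19. The gamma cluster had 1 measured gene, PCDHGB4 at 0.38 ± 0.28 (adjusted p = 0.178), so a rise of that cluster is not shown. A rise over the whole group was the hypothesis, and camera over the 5 lists gave an adjusted p of 7.98e-17 (adjusted p = 0.0765 with an estimated correlation), which passed with each line left out and under both rescalings. Alpha cluster transcripts share their last exons and the genes of a cluster resemble each other, so the probe sets may not be independent measurements.

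The rise of ASNS and SLC7A11 was set against lists of ATF4 and NRF2 targets. The 27 ATF4 targets of amino acid supply passed camera (median 0.14, adjusted p = 0.00234, adjusted p = 0.461 with an estimated correlation), with PCK2, SARS1 and MTHFD2 higher and ALDH18A1 lower. Of the 27, 5 also belong to the stress response list, and NUPR1 had been seen among the named genes. STC2, at -1.19 ± 1.70, is among the 30 genes bright in the DMSO array of line 1 alone. The line medians of the 27 targets were 0.00, 0.02 and 0.40, and without line 3 the camera adjusted p was 0.714. An ATF4 response may therefore account for the rises in line 3 and stays open in the others. The 14 NRF2 targets did not rise as a list (median -0.08, camera adjusted p = 0.191), and 0 of them were called. Their medians were below 0 in every line, and 10 of them lay below 0. SRXN1 was at -0.27 ± 0.05, GCLM at -0.29 ± 0.16 and NQO1 at -0.12 ± 0.04. Above 0 lay 4, the highest being AKR1C1 at 0.23 ± 0.34 and AKR1B10 at 0.13 ± 0.07. As a set these values argue against a shared NRF2 response behind these rises.

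The fall of ID1 and ID3 was set against 13 other BMP and SMAD targets, which did not pass (median -0.05, adjusted p = 0.393). ID2, one of them, was at -0.40 ± 0.31 (adjusted p = 0.0946), while ID4, left out of the list like ID1 and ID3, rose by 0.79 ± 0.16 (adjusted p = 0.00247), and since the list leaves out these 3 called targets and its members moved in both directions, a lower BMP output stays open. The fall of SDF2L1 was set against 18 other ER chaperone genes, of which 0 were called and which did not pass (median -0.11 with an SD of 0.143 over members, camera adjusted p = 0.348). Of the 18, 12 lay below 0 and 6 above, and 6 also belong to the stress response list tested before. The median lies above the -0.54 of SDF2L1 by more than that SD. The chaperones as a set thus had no fall of that size, and a smaller one stays open. Since SDF2L1 was picked after its fall was seen, a smaller median of other genes was likely beforehand.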
